A study of Mus musculus with 35 samples.

How the data were processed

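The labels of the series describe 35 samples of MC38, a cultured mouse colon carcinoma line, with guide RNAs against Atf7ip or Setdb1 or with no knockout. Of these, 13 are ChIP-seq samples, 5 are Hi-C samples and 17 are RNA-seq libraries. The RNA-seq libraries were analysed, and the ChIP-seq and Hi-C samples were not analysed here. By the labels, the RNA libraries form an Atf7ip set (2 wild-type libraries and 2 for each of 3 guides) and a Setdb1 set (3 wild-type libraries and 2 for each of 3 guides). Whether libraries of a group come from separate cultures or clones is not given in the sources used here, so replicates may be technical.

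For each library the authors provided raw counts per gene symbol, with no normalization, as whole numbers with a different total in each library. The last lines of every deposited table name no gene and hold reads without a feature, ambiguous reads, reads that did not align and reads that aligned to several places. The labels name STAR, Bowtie2, HTSeq, MAGeCK and bedtools for the whole series, and the mm10 build. Their roles, versions, annotation and strand setting are not given in the sources used here. Reads of overlapping or antisense genes therefore cannot be assigned with certainty, and symbols of predicted genes and of close paralogs are uncertain as well. Of 48397 symbols, 46394 were found in a table of mouse gene names and 34018 in the RefSeq annotation of GRCm38.p6, the assembly that mm10 is built from, which gave the coordinates.

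The sample of each deposited table was taken from the record that ties the tables to the samples (the deposited link). The library marks in the table names disagree with that record for 17 of 17 RNA libraries. A stated alternative, the library-name link, ties each table to the sample whose title carries the same set mark and index. It was fixed before the data were examined, together with the models, the gene lists, the rule for named genes and the alternatives. The deposited link is the main analysis, and values under the library-name link are named as such wherever they are printed. All libraries recorded as the Atf7ip set are marked as the Setdb1 set, so the Atf7ip sets of the links share no library. The Setdb1 sets share only library 8 recorded as sgSetdb1_2, which is marked as wild type of that set. A change of sign between links therefore compares different libraries, not the same libraries under other labels. Library numbers below are those of the sample titles under the link that is named.

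Counts were analysed in R 4.3.3 with edgeR 4.0.16. Within each set, genes were filtered with filterByExpr by group and scaled with TMM (trimmed mean of M values). A quasi-likelihood model with robust estimation compared the 6 knockout libraries, guides together, with the wild-type libraries. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. SE of a log2 fold change was taken as its size divided by the root of the F statistic. A model with a mean per group gave 1 contrast for each guide, with the spread shared by all groups. The difference between the effects in the Atf7ip and Setdb1 sets was tested in a joint model of all 17 libraries with the set as a term. CPM (counts scaled to a library total of 1 M) of Atf7ip and Setdb1 were scaled over all 17 libraries, and CPM of other genes within their set, with SD over libraries. Exact two-sided permutation tests compared these 2 genes and 2 mapping measures, with Benjamini-Hochberg adjustment over the 8 tests of each link. With 2 libraries against 6, the smallest exact p is 0.0357, and with 3 against 6 it is 0.0119. These tests treat the libraries as independent, although the knockouts come in guide pairs.

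Fixed lists covered H3K9 methylation and HUSH machinery, MHC class I antigen presentation, MHC class II presentation, interferon-stimulated genes, nucleic acid sensing, germline genes silenced in somatic cells, clustered protocadherins, domesticated and endogenous retroviral genes, chemokines and immune ligands, p53 targets, the integrated stress response, the cell cycle and mitochondrially encoded genes. Markers of T cells, macrophages, endothelial cells, fibroblasts and epithelial cells were listed as a check of mixed samples. Of 320 listed genes, 313 were in the tables. Lists with at least 3 tested members were compared with the other genes by camera of limma 3.58.1 on log2 CPM (prior count 2), with a preset correlation of 0.01 and, as an alternative, an estimated correlation. The self-contained test fry was run as well. Adjustment was over the lists of a comparison, and members were adjusted over all genes tested and over the list alone. The fixed rule named Atf7ip and Setdb1. It also named the 8 largest rises and 8 largest falls among called genes with a mean log2 CPM of at least 1 whose knockout libraries all lay on the same side of every wild-type library. Up to 3 members per list completed it, those with the smallest adjusted p under 0.05 or otherwise the most abundant. After the values were seen, the text was narrowed to the targeted genes and to rule genes that passed the test, because uncalled list members near 0 changed sign between settings. For 8 further called list members outside the rule, the text says that they were named after their values were seen.

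Against a group with 0 counts, a fold is given as a lower bound computed with a floor of 3 counts per library. Against 1 to 3 counts, the ratio of counts is given with its 95% Clopper-Pearson counting interval. Floors and intervals cover counting error only. The libraries held 16.6 M to 29.8 M counts on genes.

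Alternatives were RLE scaling, DESeq2 1.42.0, limma voom with the guide as a random block, no filter on low counts, a minimum log2 fold change of 1, the average of the guides in the group-means model, the joint model, leaving out each library or guide, and the other link, which was added after the data were seen for the results of the library-name link. The pipeline was tested on simulated data with 200 changed genes per comparison and a planted list of 20 genes at 1.5-fold. At 2-fold, the comparison of all guides recovered 35.8% of the changed genes in the Atf7ip set and 26.9% in the Setdb1 set under the deposited link. Under the library-name link it recovered 41.8% and 49.3%. At 4-fold, the same 4 comparisons recovered 83.3%, 63.6%, 74.2% and 81.8%, with 4, 5, 6 and 6 false calls. The planted list was recovered by camera with either correlation and by fry in the 4 comparisons. Genes and libraries were simulated independently, so these recoveries and false calls do not cover genes or guide pairs that vary together. In the data, the estimated correlation was 0.846 for mitochondrially encoded genes (Atf7ip set, deposited link). It was 0.641 for interferon-stimulated genes (Setdb1 set, library-name link).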

Results

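RNA-seq of MC38 colon carcinoma cells addressed which transcripts differ when Atf7ip or Setdb1 is targeted by CRISPR guides. Setdb1 is a histone H3 lysine 9 methyltransferase, and Atf7ip is its binding partner. Each of the 17 libraries held 16.6 M to 29.8 M counts on genes (median 23.9 M), with 21382 to 23460 genes detected. Reads without an annotated feature made up 7.02 to 13.6% of aligned reads, and reads aligned to several places 23 to 33.3%. The 10 most abundant genes took 10.1 to 28.2% of the gene counts, and mitochondrially encoded genes 0.972 to 3.50%. No T cell marker and at most 1 endothelial marker was abundant enough to be tested, and no epithelial marker exceeded 6.80 CPM (Krt18). By the library marks, Krt18 averaged 4.61 and 2.79 CPM in wild type and knockouts of the Atf7ip set, against 0.021 and 0.070 in the Setdb1 set. Fibroblast markers reached 105 CPM for Dcn, 93.2 for Acta2 and 69.5 for Col3a1, but at most 0.146 for Lum. Among macrophage markers, Cd68 reached 3.03 CPM and Lyz2 2.64. The source of this marker RNA was not tested.

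The record of which table belongs to which sample and the library marks of the tables disagreed for 17 of 17 libraries. Setdb1 mRNA (chromosome 3, 95323525 to 95357202, mm10) was lowest in the 2 libraries recorded as wild type of the Atf7ip set, at 17.7 ± 0.61 CPM (SD, n = 2). It was 31.1 ± 0.574 in the libraries recorded as sgAtf7ip_1, 25.2 ± 0.779 in sgAtf7ip_2 and 74.2 ± 8.97 in sgAtf7ip_3 (n = 2 each). The libraries recorded as sgSetdb1 held 78.7 ± 11.5 CPM (n = 6), against 91.2 ± 3.36 in the wild type of their set (n = 3), a difference that did not pass the exact permutation test (p = 0.119, adjusted p = 0.317). The log2 change of Setdb1 in that set was -0.17 ± 0.14 (SE, adjusted p = 0.943). The 6 libraries with the lowest Setdb1 under the library-name link were those marked sgSetdb1, with 24.7 ± 6.02 CPM against 70.1 ± 9.55 in their wild type (n = 3). That difference gave an exact p of 0.0119, the smallest that 84 splits allow (adjusted p = 0.0476). The test treats libraries as independent, but the knockouts come in guide pairs. The 10 splits that keep these pairs whole are too few for an exact p under 0.05.

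Atf7ip mRNA (chromosome 6, 136518789 to 136610850) was not clearly lower in the knockouts of its own set under either link. Under the deposited link it was 12.3 ± 4.23 CPM in sgAtf7ip (n = 6) and 17.1 ± 0.328 in wild type (n = 2), with an exact p of 0.0714 (adjusted p = 0.286). Its log2 change was -0.47 ± 0.34 (adjusted p = 0.504), and by guide only the libraries recorded as sgAtf7ip_3 passed, at -1.32 ± 0.13 (adjusted p = 1.4e-05). Under the library-name link it was 21.9 ± 4.43 CPM in sgAtf7ip (n = 6) and 27.0 ± 1.78 in wild type (n = 2), with an exact p of 0.179 and a log2 change of -0.31 ± 0.22 (adjusted p = 0.752). Only sgAtf7ip_2 passed by guide there, at -0.71 ± 0.12 (adjusted p = 6.8e-05). The lowest Atf7ip of any group under that link, 7.95 ± 1.87 CPM, was in the wild type of the Setdb1 set (n = 3). A knockout guide need not lower the mRNA, and the spread of Atf7ip between libraries follows neither link in full.

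**Figure D1:**
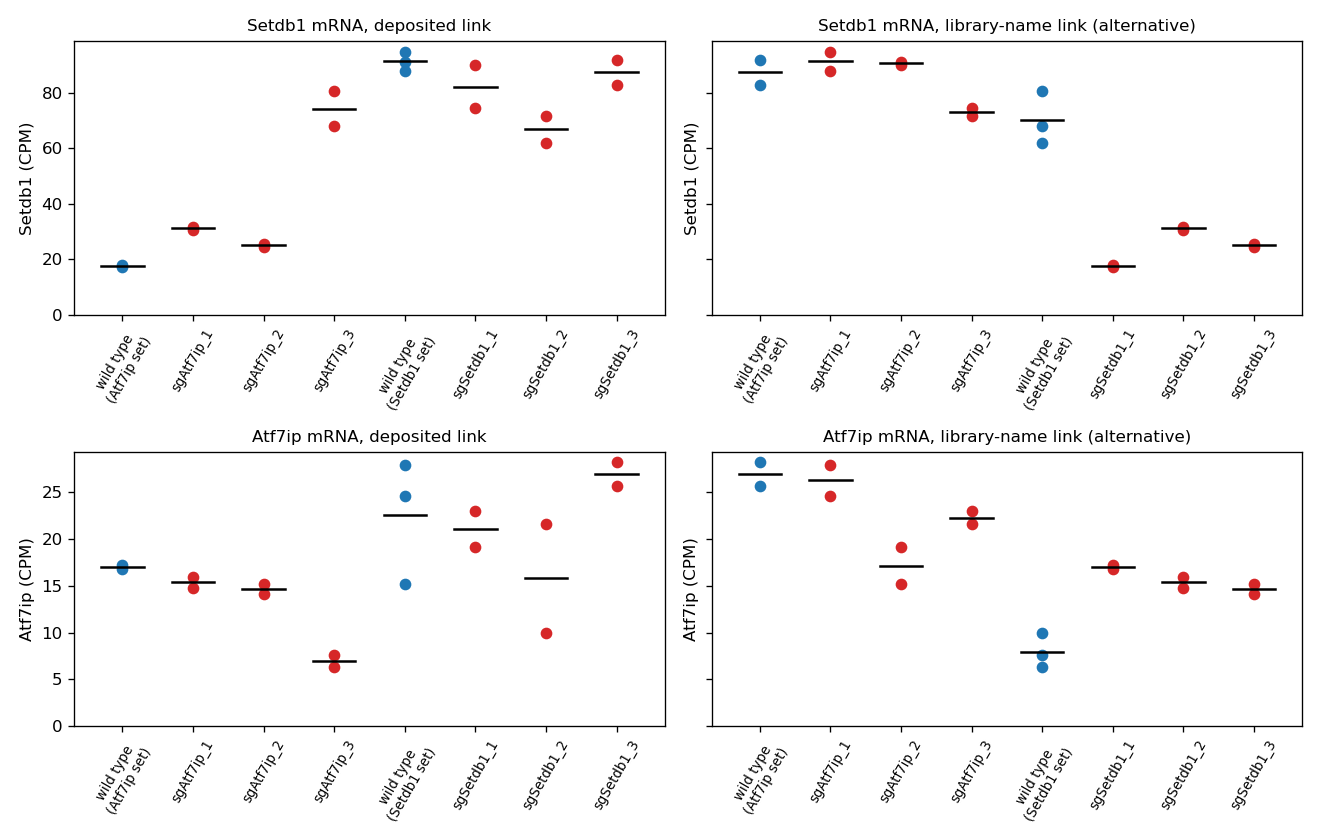
Setdb1 and Atf7ip mRNA in CPM (vertical axes) for each library, by group (horizontal axes), under the deposited link and the library-name link; points are libraries, bars are group means, blue is wild type and red is knockout. Setdb1 averages 17.7 CPM in the libraries recorded as wild type of the Atf7ip set, and under the library-name link it averages 24.7 CPM over the 6 sgSetdb1 libraries and 70.1 CPM in their wild type.

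Under the deposited link, more genes were lower than higher in the 6 libraries recorded as sgAtf7ip against the 2 recorded as wild type. Acta2, smooth muscle actin, fell from 81.1 ± 4.81 CPM (SD, n = 2) to 0.708 ± 0.327 (n = 6), a log2 change of -6.82 ± 0.26 (SE, adjusted p = 1.1e-06). Myl9, a myosin light chain, changed by -5.16 ± 0.48 and Cnn1, calponin, by -4.05 ± 0.49. Piwil2, a germline Piwi protein, changed by -6.34 ± 0.55, Spon2 by -5.32 ± 0.34, and 4930550L24Rik by -9.97 ± 0.38. Rises were fewer, with Rorb, a nuclear receptor, at 3.85 ± 0.73, Lpl, lipoprotein lipase, at 2.31 ± 0.43, and Col7a1, an anchoring fibril collagen, at 1.35 ± 0.17. Of 14729 genes tested with edgeR, 22 were higher and 210 lower. The share of higher genes, 9.48%, moved in both directions between settings. It was 40.2% with DESeq2, 32.7% in the group-means model, 37.8% without library 11 and 41.2% without guide 3. More lopsided shares were 0% in the joint model, 5.83% without library 5, 6.14% without guide 1 and 8.22% without library 4. The share was also lower with limma voom. All 232 had every knockout library on the same side of both wild-type libraries, as had 22.5% of tested genes where chance gives 7.14% for 8 independent libraries, and more if the 2 libraries of a group move together. The 2 libraries recorded as wild type are also those with the lowest Setdb1 mRNA, and their library marks name sgSetdb1_1. In the Atf7ip set of the library-name link, which holds none of these libraries, the log2 changes had the other sign for Acta2 (0.65), Piwil2 (3.17), Cnn1 (0.25), Lpl (-0.28) and Col7a1 (-0.25). Without wild-type library 1 or 3, 11 and 18 genes were called, with the lone control assumed to vary like the other group. Without library 4 or 5 of sgAtf7ip_1, 7 or 8 of sgAtf7ip_2, or 10 or 11 of sgAtf7ip_3, the counts were 146, 103, 109, 106, 79 and 1152. Of 29 called genes that the rule names, the 8 removals in that order kept 6, 9, 23, 21, 24, 23, 20 and 29. Acta2, Myl9, Piwil2, Spon2, Pdgfrb and 4930550L24Rik kept their call in each, while Cnn1, Col7a1, Lpl and Rorb lost it without wild-type library 1 and without library 3. Lpl also lost it without libraries 4, 5 or 10, and Rorb without 4, 5 or 8. DESeq2 called 784 genes, limma voom 51, the group-means model 3602 and the joint model 44, and the count without guide 1 was 114 and without guide 3 was 4128. Contrasts for single guides called 3702, 4353 and 2615 genes, with 151 higher and 573 lower in all 3. The contrasts share their wild-type libraries, so they overlap even without an effect of the guides. Different guides called 281 genes in opposite directions.

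Lists of interferon-stimulated, nucleic acid sensing and MHC class I genes were lower in the libraries recorded as sgAtf7ip than in the 2 recorded as wild type, which are marked sgSetdb1_1. The direction turned in the Atf7ip set of the library-name link, where interferon-stimulated genes had a median log2 change of 0.54 (30 of 38 above 0), Tap1 0.68, B2m 0.70, Gbp3 0.48, Ddx58 0.30, Ifih1 0.54, Eif2ak2 0.31 and Adar 0.13, while Parp14 (-0.21) and Parp9 (-0.12) kept their sign without passing. Of 40 interferon-stimulated genes tested under the deposited link, 9 fell and 0 rose, and 29 fell when adjusted over the list alone. Gbp3, an interferon-induced GTPase, fell by 1.57 on the log2 scale (SE 0.21), and Parp14 and Parp9, interferon-induced ADP-ribosyltransferases, changed by -1.27 ± 0.20 and -1.08 ± 0.12. The list differed from other genes by camera (adjusted p = 8.4e-19), with adjusted p = 0.069 with an estimated correlation. In nucleic acid sensing, 4 of 13 fell (7 over the list alone): Ddx58 (RIG-I) by -1.28 ± 0.11, Ifih1 (MDA5) by -1.24 ± 0.14, the kinase Eif2ak2 by -0.80 ± 0.11 and the RNA editor Adar by -0.55 ± 0.10, the last named after its values were seen. In MHC class I antigen presentation, 2 of 20 fell (9 over the list alone): the peptide transporter Tap1 by -1.06 ± 0.12 and the light chain B2m by -0.71 ± 0.11. Both lists passed camera (adjusted p = 9.6e-07 and 4.1e-07) and also with an estimated correlation (adjusted p = 0.015 for each). Without wild-type library 1 or 3, 0 and 1 interferon-stimulated genes were called lower by edgeR. Without library 5, 7, 8 or 10 of the knockouts it was 6, 5, 5 and 3, and without library 11 it was 18, while DESeq2 called 16, limma voom 2 and the joint model 4. The group-means model called 37 of them lower and the fit without guide 3 called 29. Without wild-type library 1 and without library 3, Tap1, B2m, Gbp3, Parp14, Eif2ak2 and Adar lost their calls, and without library 1 Parp9, Ddx58 and Ifih1 did so. B2m and Parp14 also lost theirs without library 10, and Adar without libraries 4, 5, 7, 8 or 10.

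Other lists had few called members under the deposited link of the Atf7ip set. The germline genes Piwil2 and Xlr3b (-2.49 ± 0.29) fell among 9 tested, and 2 fell and 1 rose over the list alone (camera adjusted p = 0.053, and 0.28 with an estimated correlation). Among 7 fibroblast markers, Acta2 and Pdgfrb (-2.04 ± 0.17) fell and Col1a2 rose (1.95 ± 0.37), with a camera adjusted p of 0.043 and adjusted p = 0.28 with an estimated correlation. Csf1, a macrophage growth factor, fell by 0.63 ± 0.13 as the only one of 15 chemokines and immune ligands (camera adjusted p = 0.041, adjusted p = 0.15 with an estimated correlation). The transcription factor Cebpb changed by -0.87 ± 0.14 as the only one of 14 genes of the integrated stress response (adjusted p = 0.043, and adjusted p = 0.27 with an estimated correlation). No clustered protocadherin of 11 tested was called by edgeR over all genes, 3 fell when adjusted over the list alone, and camera gave an adjusted p of 0.0093 (adjusted p = 0.069 with an estimated correlation). No member was called by edgeR among 22 cell cycle genes, 18 of the H3K9 machinery, 16 p53 targets, 9 mitochondrially encoded genes, 4 retroviral genes, 3 of MHC class II and 2 macrophage markers, with camera adjusted p of 0.079, 0.17, 0.17, 0.35, 0.40 and 0.091 for the first 6. In the Atf7ip set of the library-name link, the sign turned for Acta2 (0.65), Pdgfrb (0.090), Col1a2 (-0.32), Csf1 (0.81), Cebpb (1.05) and Piwil2 (3.17). Removing wild-type library 1 or 3 ended the calls of Xlr3b, Col1a2, Csf1 and Cebpb. Col1a2 also lost its call without libraries 4, 5, 7 or 10, and Csf1 without 5, 7, 8 or 10.

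Under the deposited link, no gene was called in the Setdb1 set. Of 15728 genes tested with edgeR, 0 passed (smallest adjusted p = 0.599), and DESeq2 called 35. With edgeR, 780 had an unadjusted p under 0.05, no more than chance gives at that threshold. Limma voom called 0. Contrasts for the 3 guides called 0 each, and DESeq2 called 1, 207 and 154. Leaving out wild-type library 3 gave 48 calls and leaving out library 4 of sgSetdb1_1 gave 40, while 17 were called without guide 1. No list member passed over all genes, and adjusted over the list alone 1 each passed among germline genes (Xlr3b), chemokines and immune ligands (Ccl5), p53 targets (Eda2r) and fibroblast markers (Col1a2).

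Several lists differed as groups in that comparison by camera with the preset correlation, and none with an estimated one. Mitochondrially encoded genes had a median log2 change of -0.52 (9 of 9 below 0, adjusted p = 3.3e-07, adjusted p = 0.41 with an estimated correlation). Epithelial markers had a median of -0.80 (adjusted p = 8.9e-05) and fibroblast markers one of 1.09 (adjusted p = 0.0048), each with adjusted p = 0.41 with an estimated correlation. Nucleic acid sensing had a median of -0.19 (adjusted p = 0.026) and interferon-stimulated genes one of -0.14 (adjusted p = 0.047), with adjusted p = 0.41 and adjusted p = 0.73 with an estimated correlation. Mitochondrially encoded genes took 2.69 to 3.50% of the counts in the 3 libraries recorded as wild type and 1.49 to 3.15% in the 6 recorded as sgSetdb1. The other lists with at least 3 tested members did not pass camera, with medians from -0.17 for the integrated stress response to 0.75 for MHC class II presentation.

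Under the library-name link, the Setdb1 set showed transcripts that were nearly silent in wild type and abundant in the 6 libraries marked sgSetdb1. Bglap3, an osteocalcin-related gene, had 3 counts in the 3 wild-type libraries and 6817 in the knockouts, a ratio of 1447 (95% counting interval 495 to 7021). Klhdc7a was at least 40.2-fold higher, and the predicted genes Gm18222, Gm20159 and Gm33962 at least 73.6-fold, 53.6-fold and 38.2-fold higher. Dnah7a, an axonemal dynein heavy chain, had a ratio of 745 (133 to 29437). Among the falls, Il33, an alarmin cytokine, went from 9.74 ± 0.534 CPM (SD, n = 3) to 0.112 ± 0.0504 (n = 6), a log2 change of -6.35 ± 0.25 (SE, adjusted p = 1.2e-07). Dcn, the matrix proteoglycan decorin, changed by -4.10 ± 0.38, Fgd4 by -4.80 ± 0.51 and the transcription factor Ikzf2 by -3.45 ± 0.45. Of 14835 genes tested with edgeR, 741 were higher and 585 lower. The share of higher genes, 55.9%, was 46.5% in the group-means model, 46.9% without guide 1 and 70.9% without guide 3. Of these calls, 1275 of the 1326 had every knockout library on the same side of all wild-type libraries, as had 14.6% of tested genes where chance gives 2.38% for 9 independent libraries, and more if those of a group move together. Setdb1 itself changed by -1.52 ± 0.19 (adjusted p = 0.00033), with -2.03, -1.19 and -1.46 for the 3 guides, and Atf7ip rose by 0.97 ± 0.15 (adjusted p = 0.0018). By the record, the Setdb1 set consists of other libraries except 1. There the sign turned without passing for Bglap3 (-1.25), Klhdc7a (-1.16), Gm18222 (-0.87), Gm20159 (-0.83), Gm33962 (-0.15), Dnah7a (-0.87), Il33 (5.22), Fgd4 (2.74), Ikzf2 (1.01) and Atf7ip (-0.050).

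Single guides of that comparison called 2198, 1706 and 2503 genes. All 3 shared 494 higher and 251 lower, with the same wild-type libraries in each contrast, which alone makes them overlap. Different guides called 42 genes in opposite directions. Removing wild-type library 2 gave 626 calls and library 3 gave 705, of which 624 and 684 were among the 1326. Limma voom called 375, all among them, the group-means model 2605, and 2022 were called without guide 1. Cbx1 lost its call without any 1 of the 9 libraries. Tex101 did so without each wild-type library and without libraries 4, 5, 10 or 11 of the knockouts, and Calr and Pcdhb22 without each wild-type library. H2-DMb1 lost it without wild-type library 2 or 3, Pcdhgb6 without library 2 and Pdia3 without library 3. Limma voom kept 31 of 45 called genes that the rule names and the joint model 35, and both ended the calls of Atf3, Chac1, Trib3, Tmem173 and Col1a1.

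Interferon-stimulated genes were higher in the libraries marked sgSetdb1, with 21 of 40 rising and 0 falling (26 and 0 adjusted over the list alone). Rsad2 (viperin), an antiviral enzyme, went from 2.77 ± 0.444 CPM (n = 3) to 9.69 ± 1.34 (n = 6), a log2 change of 1.80 ± 0.17 (adjusted p = 5.0e-05). Cmpk2, a mitochondrial nucleotide kinase beside it, rose by 3.42 ± 0.38 and the oligoadenylate synthetase Oas1a by 2.81 ± 0.37. The list had a median log2 change of 1.36 (38 of 40 above 0) and passed camera (adjusted p = 8.1e-15) and fry (adjusted p = 0.027), with adjusted p = 0.48 with an estimated correlation. Without wild-type library 2 or 3, 12 and 13 members were called higher, and limma voom called 6. Of the other lists that passed camera in that comparison, germline genes and MHC class II also passed fry (adjusted p = 0.00021 and 0.011). Fry did not pass for MHC class I, H3K9 machinery and mitochondrially encoded genes (adjusted p = 0.18 each) or the integrated stress response (adjusted p = 0.090). In nucleic acid sensing, 2 of 13 rose, Zbp1 (1.49 ± 0.26) and Tmem173, the adaptor STING (0.84 ± 0.14), 1 fell over the list alone, and camera gave an adjusted p of 0.25. The sign turned by the record for Cmpk2 (-0.85), Oas1a (-0.74) and Zbp1 (-0.89), none passing, and the interferon list had a median of -0.14 there.

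Some transcripts of antigen presentation genes were higher under the library-name link of the Setdb1 set. Of 20 MHC class I genes, 4 were called higher (5 over the list alone), and the list median log2 change was 0.12. H2-T22, a non-classical class I molecule, rose by 1.06 ± 0.13, the endoplasmic reticulum proteins Pdia3 and Calr by 0.64 ± 0.13 and 0.70 ± 0.17, and the immunoproteasome subunit Psmb9 by 0.75 ± 0.20, the last named after its values were seen (camera adjusted p = 0.025, adjusted p = 0.60 with an estimated correlation). Of 3 MHC class II genes, the peptide-loading subunit H2-DMb1 rose by 0.97 ± 0.22 (2 over the list alone, camera adjusted p = 0.020, adjusted p = 0.23 with an estimated correlation). The calls of Pdia3, Calr, Psmb9 and H2-DMb1 ended without wild-type library 3, those of Calr, Psmb9 and H2-DMb1 without library 2, and that of Calr without library 1. Psmb9 also lost its call without knockout libraries 4, 5, 8 or 10. Chemokines and immune ligands went both ways, with 2 of 15 higher and 3 lower (3 and 4 over the list alone, camera adjusted p = 0.44). The monocyte attractants Ccl2 (796 ± 66.9 to 208 ± 38.7 CPM) and Ccl7 changed by -1.94 ± 0.16 and -1.77 ± 0.25, and Ccl5 by -1.5 ± 0.31. Ulbp1, a ligand of the receptor NKG2D, rose by 2.08 ± 0.18 and Cxcl10 by 0.59 ± 0.15. Ccl5 and Cxcl10 were named after their values were seen. Ccl5 lost its call without wild-type library 3, and Cxcl10 without each wild-type library and without libraries 4, 5, 10 or 11. By the record, the sign turned without passing for H2-T22 (-0.23), Ccl2 (0.34), Ccl5 (2.12), Ulbp1 (-0.26) and Cxcl10 (-0.18).

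Germline genes and clustered protocadherins also included risers in that comparison. Of 9 germline genes, 3 rose and 1 fell. Tdrd9, a germline helicase, was at least 14.3-fold higher, Tuba3a had a ratio of 56.4 (15.4 to 469) and Tex101 a log2 change of 3.54 ± 0.81, while Magea10, named after its values were seen, changed by -2.04 ± 0.54 (camera adjusted p = 0.011, adjusted p = 0.19 with an estimated correlation). The call of Tex101 ended without each wild-type library and without libraries 4, 5, 10 or 11, and that of Magea10 without each wild-type library and without libraries 7 or 8. Of 11 clustered protocadherins, neuronal adhesion proteins, Pcdhgb2 (3.32 ± 0.53), Pcdhgb6 (2.44 ± 0.56) and Pcdhb22 (1.75 ± 0.43) rose, with reads of such close paralogs uncertain, 3 others fell when adjusted over the list alone, and camera gave an adjusted p of 0.40. Without wild-type library 2 the calls of Pcdhgb6 and Pcdhb22 ended, and without library 1 or 3 that of Pcdhb22. Tdrd9 (-1.57), Tuba3a (-1.26) and Pcdhgb2 (-0.41) had the other sign by the record, none passing.

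Of 14 genes of the integrated stress response, 4 rose in the same libraries. Atf3 (1.74 ± 0.33), Chac1 (0.64 ± 0.13), Trib3 (0.67 ± 0.14) and Ddit3 (0.45 ± 0.11, named after its values were seen) were the 4, and 5 rose over the list alone (camera adjusted p = 0.024, adjusted p = 0.60 with an estimated correlation). Among 16 p53 targets, Gdf15 (0.97 ± 0.14), Tnfrsf10b (0.55 ± 0.14) and Trp53inp1 (1.99 ± 0.43) rose and the receptor Eda2r (-2.54 ± 0.33) and Phlda3 (-0.75 ± 0.11) fell, with Tnfrsf10b and Trp53inp1 named after their values were seen (camera adjusted p = 0.14). The H3K9 machinery held Atf7ip as its only riser and Setdb1 and Cbx1 (-0.32 ± 0.09) as its fallers among 18 (camera adjusted p = 0.032, adjusted p = 0.60 with an estimated correlation). No member of 9 mitochondrially encoded genes passed over all genes with edgeR, 2 did over the list alone, and camera gave an adjusted p of 0.018 (adjusted p = 0.60 with an estimated correlation). Neither 22 cell cycle genes nor 4 retroviral genes had a member called over all genes, and 1 retroviral gene fell over the list alone (camera adjusted p = 0.18 and 0.24). Among 7 fibroblast markers, Dcn fell and Col1a1 rose (1.09 ± 0.20), with a median of -0.61, a mean of 0.08 and a camera adjusted p of 0.40, and of 2 macrophage markers Lyz2 rose (2.49 ± 0.47, to 1.83 ± 0.545 CPM). Calls ended without wild-type library 2 or 3 for Ddit3, Tnfrsf10b and Trp53inp1, without libraries 10 or 11 for Ddit3, without 4, 5, 10 or 11 for Tnfrsf10b, and for Cbx1 without any 1 of the 9 libraries. Chac1 (-0.35), Trib3 (-0.27), Gdf15 (-0.22), Eda2r (1.86), Phlda3 (0.65) and Cbx1 (0.15) had the other sign by the record, none passing.

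**Figure D2:**
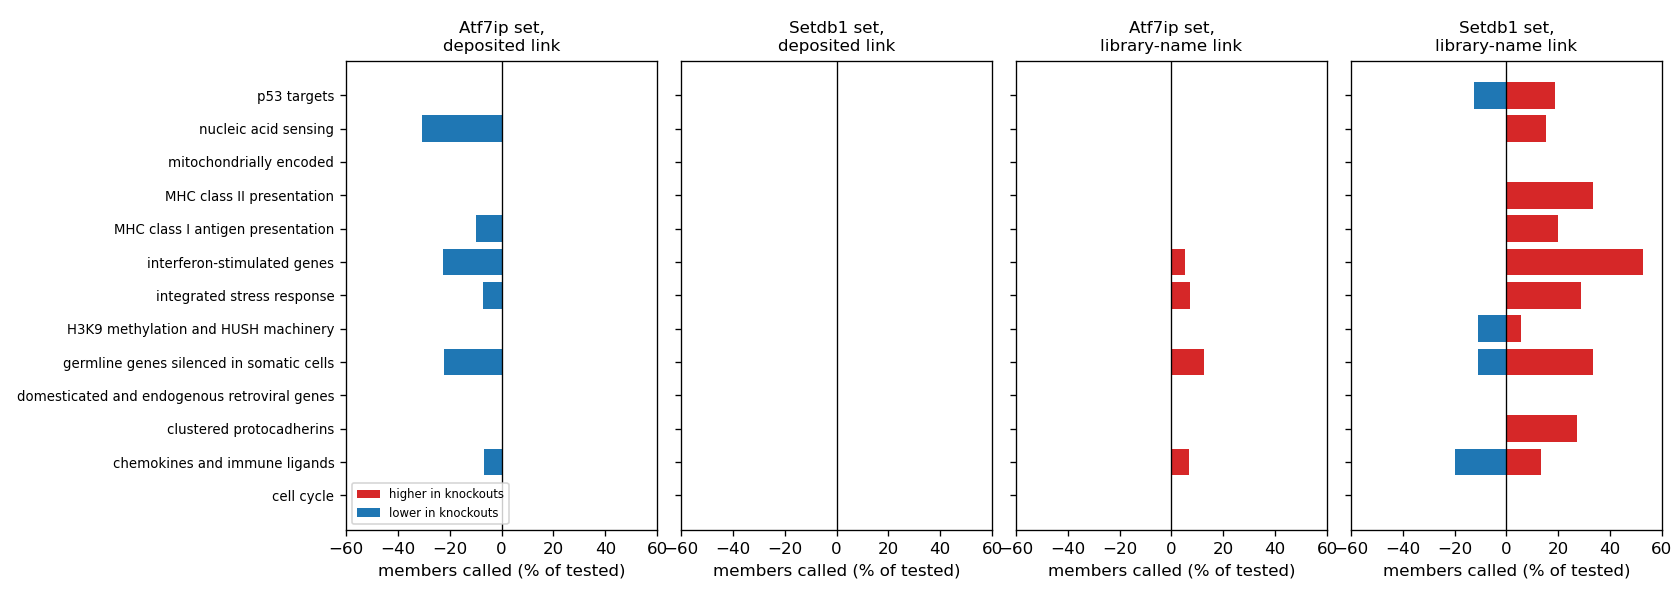
Share of tested members of each fixed list called higher (red, to the right) or lower (blue, to the left, drawn as negative) in knockouts, in percent of tested members on the horizontal axis, for both sets under both links; bars start at 0. Interferon-stimulated genes show 9 of 40 lower in the Atf7ip set under the deposited link and 21 of 40 higher in the Setdb1 set under the library-name link.

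Fewer genes were called in the Atf7ip set under the library-name link. Acvrl1, a receptor of the TGF-beta family, went from 2.21 ± 0.424 CPM (SD, n = 2) to 22.3 ± 0.405 (n = 6), a log2 change of 3.33 ± 0.18 (SE, adjusted p = 2.7e-05). The growth factor Fgf10 rose by 3.43 ± 0.54, the glutathione transferase Gstp2 by 4.41 ± 0.65 and Fbxw23 by 5.63 ± 0.53. Among the falls were Gas7 (-5.24 ± 0.69), Ddit4l, an inhibitor of mTOR signalling (-2.85 ± 0.30), the repressor Bhlhe41 (-2.07 ± 0.32) and the receptor Fgfr1 (-1.28 ± 0.23). Of 15587 genes tested with edgeR, 58 were higher and 22 lower. The share of higher genes, 72.5%, was 55.9% in the group-means model and 84.1% without guide 1. By the record, the sign turned without passing for Acvrl1 (-2.38), Fgf10 (-0.79), Gstp2 (-0.40), Fbxw23 (-0.53), Gas7 (3.38), Ddit4l (1.24) and Bhlhe41 (1.10). DESeq2 called 433, limma voom 5, the group-means model 2937, the joint model 227, and the fits without guide 1, 2 or 3 called 334, 211 and 134. Without wild-type library 1 or without library 3, 1 gene was called, Acvrl1 (adjusted p = 0.0013 and 0.0026), with the lone control assumed to vary like the other group. Without library 4 of sgAtf7ip_1, the calls of Fgfr1, Cmpk2, Gsap, Tdrd9 and Vldlr ended, and that of Fgfr1 also without libraries 5, 7 or 8.

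Of 38 interferon-stimulated genes in that comparison, 2 rose, Oas1a (3.74 ± 0.54) and Cmpk2 (3.25 ± 0.56), and 10 rose when adjusted over the list alone. The list passed camera (adjusted p = 8.3e-07), with adjusted p = 0.49 with an estimated correlation, and without wild-type library 1 or without library 3, 0 members were called by edgeR. DESeq2 called 9 of them, limma voom 0, the joint model 5 and the group-means model 17. Fry did not pass for this list (adjusted p = 0.16), nor for MHC class I or mitochondrially encoded genes (adjusted p = 0.13 and 0.19). It passed for germline genes (adjusted p = 0.0057). Oas1g, another oligoadenylate synthetase, rose by 5.02 ± 0.77. Ulbp1 rose by 2.50 ± 0.27 among 15 chemokines and immune ligands, the lipoprotein receptor Vldlr by 1.23 ± 0.19 among 14 genes of the integrated stress response, and Tdrd9 was at least 15-fold higher among 8 germline genes (camera adjusted p = 0.29, 0.37 and 0.24). These calls also ended without wild-type library 1 or 3, and those of Tdrd9, Vldlr and Cmpk2 without library 4. The sign turned by the record, none passing, for Oas1a (-1.60), Cmpk2 (-1.25), Oas1g (-1.54), Ulbp1 (-0.85), Vldlr (-0.33) and Tdrd9 (-1.29). No member of MHC class I (20 tested) or of the mitochondrially encoded genes (9) was called over all genes with edgeR, 1 of each was over the list alone, and camera gave adjusted p of 0.018 and 2.7e-05, each with adjusted p = 0.49 with an estimated correlation. No member was called over all genes among clustered protocadherins, nucleic acid sensing, p53 targets, H3K9 machinery, cell cycle, MHC class II, retroviral genes, fibroblast markers and epithelial markers. These lists did not pass camera (adjusted p from 0.095 to 0.83), and over the list alone 1 protocadherin and 1 retroviral gene rose and, among p53 targets, 1 rose and 2 fell. The fibroblast list had a median of 0.34 and the retroviral list one of -0.19, each with a camera direction of the other sign. For MHC class II the median was -0.25, the mean 0.15 and the direction down, and for the cell cycle they were -0.01, 0.01 and down. Contrasts for single guides called 2123, 5074 and 4363 genes, with 390 higher and 171 lower in all 3, again against shared wild-type libraries. Different guides called 640 genes in opposite directions.

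The sets overlapped under the library-name link. Of 57 genes higher in the Atf7ip set and tested in both, 48 were also higher in the Setdb1 set, where 2.75 would be shared by chance (Fisher's exact p = 7.8e-55), and of 21 lower genes 16 were shared (0.855 by chance, Fisher's exact p = 7.9e-19). No gene was called in opposite directions. The overlap rests on the 80 calls of the Atf7ip set with 2 wild-type libraries, of which limma voom with the guide as a block kept 4. The shared genes included Acvrl1, Ulbp1, Oas1a, Cmpk2, Fgf10 and Tdrd9 among the risers and Fgfr1, Gas7, Ddit4l and Bhlhe41 among the fallers. Log2 changes of the sets had a Pearson correlation of 0.81 and a Spearman correlation of 0.50 across 10709 genes, and the sets share no library. The genes are not independent replicates, although Fisher's exact test treats them as such. Under the deposited link the Spearman correlation was 0.50 too, so it does not tell the links apart. The test of the difference between the effects called 0 of 16532 genes with edgeR, and DESeq2 called 18. With edgeR, 690 had an unadjusted p under 0.05, fewer than chance gives at that threshold. In simulated data that test recovered 22.4% of 2-fold and 62.1% of 4-fold differences.

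Under the deposited link, the effects differed between the sets for 15 of 16532 genes, with the effect higher in the Setdb1 set for each. Acta2 differed by -8.56 ± 0.84 on the log2 scale (Atf7ip effect minus Setdb1 effect, adjusted p = 8.0e-05), Myl9 by -6.43 ± 0.98, Cnn1 by -5.61 ± 0.84 and Pdgfrb by -2.43 ± 0.44. The Atf7ip effect is measured against 2 recorded wild-type libraries that are marked sgSetdb1_1. Acta2 was at 81.1 CPM in these and at 0.708 in the 6 recorded as sgAtf7ip. The differences therefore need not reflect unlike effects of targeting Atf7ip and Setdb1. DESeq2 called 36, and with edgeR 575 had an unadjusted p under 0.05, fewer than chance gives at that threshold. With 0 genes called by edgeR in the Setdb1 set, no overlap could be counted. The Pearson correlation of log2 changes across 10745 genes was 0.49 and the Spearman correlation 0.50.

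**Figure D3:**
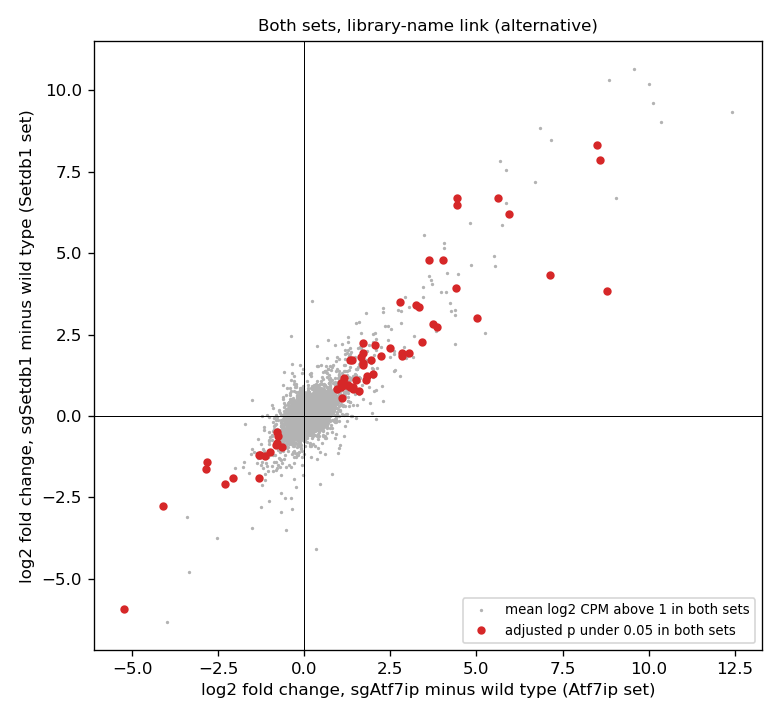
Log2 fold change in the Setdb1 set (vertical axis) against that in the Atf7ip set (horizontal axis) under the library-name link, for genes with a mean log2 CPM above 1 in both sets (grey) and, in red, genes with an adjusted p under 0.05 in both. The red points comprise 48 genes higher in both sets and 16 lower in both, and none has opposite directions.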

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

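The test of library marks that carry no group was chosen only after the result was seen. In 20 tests for a library far from the others among 6 knockout libraries of a set, chance picks about 1 in 20, and 3 libraries stood apart. The share of aligned reads without a feature was 7.02% in library 11 recorded as sgAtf7ip_3, against 9.41% in the nearest of the others. Gene counts were 17.2 M in library 8 recorded as sgSetdb1_2, against 23.9 M in the nearest. With the library-name link, the share without a feature was 8.72% in library 4 of sgSetdb1_1, against 10.2% in the nearest.

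Under the deposited link, the test of the difference between the sets called 15 genes, each with a higher effect in the Setdb1 set. They were 4930550L24Rik, Acta2, Cnn1, Myl9, Xlr3b, Spon2, Cp, Rhox2d, Efcab6, Fam210b, Pdgfrb, Inadl, Egr2, Actg2 and Atp13a5. Those outside the rule for named genes were listed after their values were seen. The wild type of the Atf7ip set in that test is the 2 libraries marked sgSetdb1_1, so unlike effects of the targeted genes are not shown.

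The record and the library marks disagree for 17 of 17 RNA libraries, and libraries of a group had a mean Pearson correlation of log2 CPM of 0.990 under the library-name link and 0.974 under the deposited link, over 10926 genes, and the highest of 100 random links within the sets gave 0.983 for the former, which argues against library marks that carry no group. The deposited link was matched by 1 of its own 100 random links (highest 0.976), but 6 of its 10 same-group pairs are also pairs under the marks. Pairs that share a group under the record alone correlated at 0.921 to 0.961 and pairs that do so under the marks alone at 0.974 to 0.995, and the nearest library was of the same group for 11 of 17 under the record and 16 of 17 under the marks. These values argue against the record as it stands, and a candidate explanation that they fit is that the tables were attached to the samples in another order than their titles. What stays open is whether each mark names the right guide, because the guides' edits were not examined here, Atf7ip mRNA follows neither link in full, and no biological explanation was tested.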

How the results depend on the processing

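The deposited link as an alternative to the library-name link was chosen after the data were seen, and 8 genes named after their values were seen were run under the same settings. No paired analysis was possible because library numbers are not shared between a wild type and its knockouts in either RNA set, and the ChIP-seq libraries that share numbers were not analysed here. The cause of the differences below was not tested, except that a minimum log2 change of 1 removes smaller effects by construction. Leaving out a wild-type library leaves a lone control in the Atf7ip set. Simulated 1.5-fold changes were recovered by the comparison of all guides in 0 to 11.9% of cases.

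For the Atf7ip set under the deposited link (232 calls), the count was 153 with RLE, 784 with DESeq2, 51 with limma voom, 3602 in the group-means model, 44 in the joint model, 114 without guide 1, 4128 without guide 3, 116 with a log2 change of at least 1, 80 under the library-name link (6 shared), and 11 to 1152 without 1 library. The Setdb1 set under that link had 0 calls with edgeR, and 780 at an unadjusted p under 0.05, no more than chance gives. It gave 35 with DESeq2, 17 without guide 1, 1326 under the library-name link and 0 to 48 without 1 library. Its guides gave 1, 207 and 154 with DESeq2. With the library-name link, the Atf7ip set (80) gave 433 with DESeq2, 5 with limma voom, 136 with no filter, 2937 in the group-means model, 227 in the joint model, 334, 211 and 134 without guide 1, 2 or 3, 232 under the deposited link, and 1 to 80 without 1 library. The Setdb1 set (1326) gave 375 with limma voom, 2605 in the group-means model, 2022 without guide 1, 655 with a log2 change of at least 1, 0 with edgeR under the deposited link, and 626 to 1199 without 1 library. The difference between sets gave 36 with DESeq2 under the deposited link, and 3 with no filter and 18 with DESeq2 under the library-name link. Camera called 12 lists under the deposited link and 10 under the library-name link, and 2 and 0 with an estimated correlation. The fry test, whose lists need not be the same, called 8 and 4, and 8 and 16 in either direction.

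Signs under the 2 links come from different libraries, since the Atf7ip sets share none and the Setdb1 sets share 1. Against the deposited link, log2 changes of the Atf7ip set under the library-name link had the other sign for 20 genes: Setdb1 -0.057, Lpl -0.28, Gm44143 -0.29, Col7a1 -0.25, Snord118 -0.40, Col1a2 -0.32, Acta2 0.65, Piwil2 3.17, Cnn1 0.25, Slc47a1 3.70, Tap1 0.68, B2m 0.70, Gbp3 0.48, Ddx58 0.30, Ifih1 0.54, Eif2ak2 0.31, Adar 0.13, Csf1 0.81, Cebpb 1.05 and Pdgfrb 0.090. Atf7ip in the Setdb1 set under the deposited link turned to 0.15 without wild-type library 2, 0.06 without library 8, 0.087 without guide 2 and 0.97 under the library-name link. Setdb1 in the Atf7ip set under the library-name link turned to 0.023 without guide 3. Against the library-name link, the deposited link turned the sign of 18 named genes of the Atf7ip set: Setdb1 1.29, Fbxw23 -0.53, Oas1g -1.54, Gstp2 -0.40, Oas1a -1.60, Gm8493 -0.63, Fgf10 -0.79, Acvrl1 -2.38, Gas7 3.38, Ddit4l 1.24, Lbh 0.67, Bhlhe41 1.10, Oaf 0.60, Arhgap28 0.045, Cmpk2 -1.25, Tdrd9 -1.29, Ulbp1 -0.85 and Vldlr -0.33. In the Setdb1 set it turned 32: Atf7ip -0.050, Gm18222 -0.87, Bglap3 -1.25, Gm20159 -0.83, Klhdc7a -1.16, Gm33962 -0.15, Gm2182 -0.72, Gm18348 -0.85, Dnah7a -0.87, Il33 5.22, Fgd4 2.74, Rab15 3.32, Medag 1.55, Ikzf2 1.01, Fyb 3.30, Cbx1 0.15, H2-T22 -0.23, Cmpk2 -0.85, Oas1a -0.74, Zbp1 -0.89, Tuba3a -1.26, Tdrd9 -1.57, Pcdhgb2 -0.41, Ccl2 0.34, Ulbp1 -0.26, Eda2r 1.86, Gdf15 -0.22, Phlda3 0.65, Chac1 -0.35, Trib3 -0.27, Ccl5 2.12 and Cxcl10 -0.18. In the alternatives run, other values of named genes kept their direction, and 145, 70 and 131 of them lost their call in the deposited Atf7ip set and in the Atf7ip and Setdb1 sets under the library-name link.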

Other observations

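The classes of genes below, the neighbour counts for genes that fell, the splits that keep guides whole and the tests of dominant genes and of RNA from immune cells were chosen only after the result was seen. Among symbols of vomeronasal and olfactory receptors, 13 of 15 tested were higher and 0 lower in the Setdb1 set under the library-name link, with reads of such close paralogs uncertain. Genes of that family near silence are tested only where some group expresses them, so this share says nothing about the family as a whole.

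Interferon-stimulated genes rose in the 6 libraries marked sgSetdb1 under the library-name link. Of 84 splits of the 9 libraries into 3 and 6, 1 (the real one) called 21 list members higher and the others at most 0, but the knockout libraries come in guide pairs, and the 10 splits that keep these whole are too few for a share under 0.05 (highest other 0), while limma voom with the guide as a block called 6. A difference in depth is argued against, since 18 of the 21 stayed called with every library thinned to 16.6 M counts, and so are a few dominant genes, since the share of the 18 largest can shift all others by at most 0.28 between a knockout and a wild-type library, against a list median of 1.36. RNA from immune cells stays open: the 16 macrophage and T cell markers averaged 0.310 CPM in the knockouts (scaled over all 17 libraries), Lyz2 was called higher (0.319 to 2.01 CPM) and Ptprc went from 0.0636 to 0.234, while Cd68 went from 2.06 to 1.87 and C1qa and Cd3e had 0. Higher interferon signalling with loss of Setdb1 may also account for the rise, which was not tested, and the list gave adjusted p = 0.48 with an estimated correlation.

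For the count of called genes in the same comparison, 2 of 84 splits, the real one included, gave as many as the real 1326. Both are among the 10 splits that keep the guides whole, so 2 of these 10 gave as many. These 10 are too few for a share under 0.05. The other split, with 2529, sets wild-type library 3 and both sgSetdb1_1 libraries against the rest, which points to a structure of the samples beyond the groups. Under the deposited link, the real split of the Setdb1 set called 0 genes with edgeR and 35 with DESeq2. At an unadjusted p under 0.05 edgeR gave 780, no more than chance gives. All 84 of 84 splits call at least 0 by definition, so the count of calls says nothing about chance. The highest other split called 478, with sgSetdb1_1 library 5 and both sgSetdb1_2 libraries against the rest, which points to a structure of the samples there too. By the marks, these are both sgAtf7ip_3 libraries and the only library there marked as the Setdb1 set. A further split called 88, with sgSetdb1_2 library 8 and both sgSetdb1_3 libraries, all marked wild type, against the rest. The recorded groups thus mix libraries that the marks keep apart.

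Genes that rose in the Setdb1 set under the library-name link lay next to each other more often than by chance. Of adjacent tested pairs, 84 had both genes higher, against a mean of 30.4 and a 95th percentile of 39 in 10000 random draws (permutation p = 1e-04, the smallest they can give). Reads shared between overlapping genes or genes with a shared symbol stem are argued against as the whole cause. Without such neighbours 57 pairs remained, against 25.3 by chance, with positions for 85.3% of the genes. Paralogs with unlike symbols stay open, because the rule compares symbols only. It kept Ifi204 beside Mndal and Gsta2 beside the predicted gene Gm10639, and the similarity of their sequences was not checked. Rsad2 and Cmpk2 on chromosome 12 were also among the 57 pairs. Derepression of neighbouring genes together may contribute, but genes that fell were clustered too. Among all adjacent pairs, 57 had both genes lower, against 24.2 by chance, and 47 against 20.1 without shared stems or overlaps. Genes that fell in the Atf7ip set under the deposited link gave 15 against 3.16, and 10 against 2.64 without such neighbours. Adjacency is therefore not particular to the risers.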
